A study of Mus musculus with 27 samples.

How the data were processed

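Total RNA of mouse bone marrow cultures was measured on 27 one-colour Affymetrix arrays. Per the labels' protocols, bone marrow cells of C57BL/6 mice received Flt3-L at about 200 ng/ml from transfected B16 cells. CsA at 2 µg/ml was added 30 min before Flt3-L and kept in the culture. RNA was extracted with Trizol, amplified with a whole transcript expression kit and labelled with biotin. The deposited intensity values are probe set signals that the authors summarised and normalized across arrays with RMA, per the submitters' processing notes, which give no version. They run from 5.2 to 18180.7, a linear scale, and log2 was taken here before any test. The plan had assumed deposited log2 values. Whether the unstimulated cells were taken fresh or kept in culture is not stated in the labels.

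The table held 28815 probe sets. Genes came from the platform's annotation, which can be old: 23385 probe sets were listed with a gene, 21780 with a single symbol and 1605 with several, and 5430 were not named. Probe sets with several symbols were left out. For 998 genes with more than 1 probe set, the probe set with the highest mean over the 27 arrays was taken, which left 19935 genes. Among called genes with several probe sets, another probe set had the opposite sign for 14 of 90 at 12 h, 5 of 38 at 24 h, 3 of 43 at 48 h and 11 of 112 at 11 days in the CsA comparisons, E2f3 at 12 h and Dpep2 at 24 h and 48 h among the named genes.

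Group means of 9 groups of 3 arrays were fitted with limma 3.58.1 in R 4.3.3, with empirical Bayes variances and Benjamini-Hochberg adjustment over the genes of each comparison. The comparisons were CsA against Flt3-L alone at 12 h, 24 h, 48 h and 11 days, Flt3-L alone against unstimulated cells at the same times, the mean CsA effect, the CsA effect at 11 days minus the mean of the 3 earlier effects, and an F test of the 4 effects. A gene was called at an adjusted p under 0.05. Errors are SE from that fit, and the number of arrays limits the precision. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

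The comparisons, 28 gene lists and the rule for named genes were fixed before the data were examined. The lists had 556 entries, of which 512 were tested. Cdkn1a lay only on a probe set shared with another gene and was not tested, and Faim3 was matched by its present symbol Fcmr. The lists cover progenitor, primary granule, late neutrophil, monocyte and macrophage, conventional and plasmacytoid dendritic cell, B lineage, T and NK cell, erythroid, megakaryocyte, mast cell with basophil and eosinophil, and stromal genes. They also cover calcineurin and NFAT pathway components, genes commonly induced through NFAT, G1 and S phase, G2 and M phase, CDK inhibitor, p53 target, interferon and inflammatory genes. Further lists were stress response (unfolded protein and integrated stress), NRF2, glycolysis, cholesterol, lysosome, cytokine receptor, transcription factor and ribosome biogenesis genes. The CDK inhibitor list also holds the pocket protein genes Rb1, Rbl1 and Rbl2. The cytokine receptor list also holds genes grouped as STAT responses, Mcl1 among them. The transcription factor list holds myeloid and dendritic cell transcription factors only. Each list was tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation. The fry tests were run beside it. PValue asks whether a list's genes move on balance in 1 direction, and PValue.Mixed whether they change in either.

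Named genes were, in each CsA comparison, the 10 largest rises and 10 largest falls among called genes whose 3 CsA arrays all lay on one side of the 3 arrays without it. The Flt3-L comparisons gave 5 and 5 by the same rule, and the mean and difference 5 and 5 without the condition on single arrays. Predicted genes, numbered clones, small RNA genes, receptor families of smell and immune receptor segments were left out. So were all symbols starting with Rn, protein-coding genes among them. Cdk4, Cdk6, Ccnd1, Ccnd2, Ccnd3, Nfatc1 to Nfatc4, Rcan1, Ppp3ca and Ppp3cb were added in every CsA comparison, and from each list described up to 4 members with the largest absolute change.

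Whether replicate numbers pair arrays was checked by correlating, across genes, the deviations of arrays with equal numbers from their group means. All pairs exceeded 0.1 for CsA at 24 h (0.37, 0.35 and 0.40) and 48 h (0.54, 0.18 and 0.19) and for Flt3-L at 12 h (0.20, 0.14 and 0.10) and 24 h (0.35, 0.13 and 0.18). However, at 48 h CsA arrays 2 and 3 correlated more with an array of another number (0.23 and 0.22). So did array 2 for Flt3-L at 24 h (0.17). The labels state no pairing, so no block entered the model reported. Alternatives were other variance models, a filter on dim genes (the third with the lowest mean left out), quantile normalization again, subtraction of each array's median, only the groups compared, the mean of a gene's probe sets, array weights, a replicate block and leaving out each array. The steps were tested on simulated data with changes added to the CsA comparison at 11 days. Of 50 genes each, 23 were called at a log2 change of 0.25, 42 at 0.5 and 50 at 1 and at 2, with 12 false among 177 calls and 0 calls in a comparison without added changes. In the CsA comparison at 12 h, a list shifted by 0.3 in simulated data was called and no other was. Simulated genes were drawn independently of each other, so this does not show how often lists of correlated genes are called falsely. Each gene had the same spread on every array, and arrays of a number shared nothing. The share of false calls therefore holds for that setting only.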

Results

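Gene expression was measured on Affymetrix arrays in bone marrow cells of C57BL/6 mice. The cells were grown with Flt3 ligand (Flt3-L), a cytokine that drives progenitors toward dendritic cells and other myeloid cells. Cyclosporin A (CsA), given to some of the cultures, blocks calcineurin, the phosphatase that lets NFAT transcription factors enter the nucleus. The 27 arrays formed 9 groups of 3 biological replicates: unstimulated cells, cells kept with Flt3-L for 12 h, 24 h, 48 h or 11 days, and cells kept with Flt3-L and CsA for the same times. Array medians lay between 114.2 and 124.8 on the linear intensity scale. The correlation between arrays of a group, across probe sets, was at least 0.996, and 25 of the 27 arrays lay closest to an array of their own group. The exceptions were the third CsA array at 12 h and the third CsA array at 24 h, each of which lay closest to the third array without CsA at the same time. A first principal component with 73.6% of the variance ordered the groups by time in culture, and the second held 10.5%. In all, 19935 genes were tested in 1 limma model over the 27 arrays, and a gene was called at an adjusted p below 0.05. Changes below are log2 differences ± SE with 3 arrays per group, and the number of arrays limits their precision. Gene lists were written down beforehand and tested with camera at a preset correlation. Each list call that was lost with an estimated correlation is given with that second adjusted p. In the list names used, cytokine receptor includes STAT response genes and CDK inhibitor includes pocket proteins. The transcription factor list holds those of myeloid and dendritic cells.

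Culture with Flt3-L for 12 h was compared with unstimulated cells to describe the cultures that those with CsA were set against. The labels do not state whether the unstimulated cells were fresh or kept in culture, so effects of the ligand and of time in culture were not separated here. The macrophage gene Gpnmb rose 30.1-fold (4.91 ± 0.07), the potassium channel gene Kcnma1 81.1-fold (6.34 ± 0.10), the lectin Clec4n 12.2-fold (3.61 ± 0.13) and the peptidase Dpep2 10.7-fold (3.42 ± 0.05). Fosb was 13.2-fold, Ptgs2 9.12-fold and Hspa1a 8.02-fold lower than in unstimulated cells. Cell cycle expression declined as a group: 23 of 25 G1 and S phase genes were lower (24 lower and 1 higher adjusted over the list alone), among them Ccne1 and Cdc6, as were 20 of 20 G2 and M phase genes (20 adjusted over the list alone), among them Bub1 and Cdk1. The G2 and M call was lost at adjusted p = 0.074 with an estimated correlation. Genes for making ribosomes fell too, 17 of 18 (17 adjusted over the list alone), with Nop58, Nolc1 and Dkc1 among the largest changes. Cholesterol synthesis genes rose in 16 of 17 cases (16 adjusted over the list alone), led by Hmgcs1 and by Msmo1 at 1.23 ± 0.07. Lysosome genes rose in 15 of 17 and fell in 1 (the same counts adjusted over the list alone), led by Lipa and Ctss. Of 28 lists, 12 were called, and the G1 and S phase, cholesterol, lysosome and ribosome lists also held with an estimated correlation. Calls lost that way were the lower erythroid genes (11 of 16, Car1 and Klf1 first, adjusted p = 0.084 with an estimated correlation) and the lower T and NK cell genes (11 of 19, Ncr1 first, adjusted p = 0.085 with an estimated correlation). The same held for lower stromal genes (10 of 17, Sparc and Cxcl12, adjusted p = 0.1 with an estimated correlation) and lower megakaryocyte genes (4 of 12, Tubb1 and Gp9, adjusted p = 0.41 with an estimated correlation). It held as well for higher NRF2 genes (12 of 17, Slc7a11 and Srxn1, adjusted p = 0.074 with an estimated correlation). Higher monocyte and macrophage genes (12 of 22, Gpnmb and Msr1) and cytokine receptor genes (10 of 21, Csf2rb2 and Il7r) were lost at adjusted p = 0.28 with an estimated correlation, and the cytokine receptor call also ended in a fit of only the groups compared. With a filter on dim genes the T and NK cell, megakaryocyte and stromal calls ended. Adjusted over the list alone these 7 lists had the same counts. Members called the other way were 5 monocyte and macrophage, 4 cytokine receptor, 3 NRF2, 1 T and NK cell and 1 stromal gene. In total 3554 genes were higher and 3615 lower, of which 135 and 221 changed at least 2-fold, but 4540 were higher and 4076 lower with array weights.

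At 24 h more macrophage genes were higher than in unstimulated cells. Trem2 was 5.4-fold higher (2.43 ± 0.07), Ms4a7 5.16-fold and C3ar1 15.7-fold, and 15 of 22 monocyte and macrophage genes were higher with 1 lower (16 and 1 adjusted over the list alone, median 1.13). The dendritic cell genes Itgax and Clec10a were 1.91-fold and 2.55-fold higher, and their list was called, a call lost at adjusted p = 0.12 with an estimated correlation (16 of 24 higher). Erythroid genes fell in 15 of 16 cases (15 adjusted over the list alone), with Car1 26.7-fold and Klf1 8.03-fold lower. Division genes stayed low, and 20 of 20 G2 and M phase genes (Birc5, Aurka) and 23 of 25 G1 and S phase genes (Tyms, Ccne1) were called lower (20 and 23 adjusted over the list alone). Of 17 list calls, 8 held with an estimated correlation: monocyte and macrophage, T and NK cell (14 of 19 lower, 16 adjusted over the list alone, Il2rb and Ncr1), erythroid, G1 and S phase, G2 and M phase, cholesterol (16 of 17 higher), lysosome (16 of 17 higher, Lipa and Ctss) and ribosome (15 of 18 lower, 17 adjusted over the list alone). The cholesterol and lysosome counts were the same adjusted over the list alone. Primary granule genes (7 of 12 lower, Prtn3 and Mpo) were lost at adjusted p = 0.11 with an estimated correlation. Plasmacytoid dendritic cell genes (9 of 17 higher, Ccr9 and Siglech), p53 targets (12 of 18 higher, Trp53inp1 and Sesn2) and cytokine receptor genes (10 of 21 higher, Csf1r and Flt3) were each lost at adjusted p = 0.15 with an estimated correlation. Stromal genes (11 of 17 lower, Sparc and Cxcl12), NRF2 genes (11 of 17 higher, Hmox1 and Srxn1) and glycolysis and hypoxia genes (9 of 18 higher, Bnip3 and Vegfa) were lost at adjusted p = 0.068, adjusted p = 0.079 and adjusted p = 0.33 with an estimated correlation. The mast cell, basophil and eosinophil list (7 of 16 lower, Epx and Fcer1a) was lost at adjusted p = 0.25 with an estimated correlation and without either of 2 arrays (adjusted p up to 0.116, without Flt3-L 24 h array 1). The mast cell call also ended with either other normalization and with array weights, and the glycolysis call with the mean of a gene's probe sets. With a filter on dim genes the mast cell and stromal calls ended. When adjusted over the list alone, the counts were 12 for stromal, 11 for glycolysis, 10 for plasmacytoid, 8 for primary granule and 12 for cytokine receptor genes, and the same for the rest. Calls in the other direction were 6 for cytokine receptor, 4 for p53, 2 each for plasmacytoid and NRF2, and 1 each for primary granule, conventional dendritic cell, T and NK cell, mast cell, stromal, G1 and S phase, glycolysis and lysosome genes. Counts were 3565 genes higher and 3538 lower, with 245 and 413 beyond 2-fold, and 3203 higher and 3736 lower with each array's median subtracted.

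By 48 h the matrix protease Mmp12 had risen 46.5-fold (5.54 ± 0.13), the peptidase Anpep 33.9-fold (5.08 ± 0.09) and the proton pump gene Atp6v0d2 23.3-fold (4.54 ± 0.11). Monocyte and macrophage genes were higher in 18 of 22 cases (20 adjusted over the list alone), conventional dendritic cell genes in 20 of 24 (20 adjusted over the list alone, Ccl22, Itgax and Tlr3), and lysosome genes in 16 of 17 (16 adjusted over the list alone, Ctsl and Lipa). Granulocyte progenitor genes fell, 11 of 12 primary granule genes (11 adjusted over the list alone) with Nkg7 6.71-fold and Ms4a3 4.14-fold lower. Genes of mast cells, basophils and eosinophils fell in 11 of 16 cases (11 adjusted over the list alone), with Epx 9.13-fold and Mcpt8 4.02-fold lower. G1 and S phase genes were lower in 22 of 25 cases and higher in 2, and G2 and M phase genes lower in 20 of 20. Cyclin D1 (Ccnd1) was among the higher, at 3.11-fold, and the inhibitors Cdkn2c and Cdkn2d were 2-fold and 1.9-fold lower. Calls for 19 lists were made and 11 held with an estimated correlation. Those were the monocyte and macrophage, conventional dendritic cell, lysosome, primary granule, mast cell, T and NK cell and erythroid genes. The others that held were the G1 and S phase, G2 and M phase, CDK inhibitor and pocket protein (5 of 9 lower, 1 higher) and cholesterol genes. Lost were plasmacytoid dendritic cell genes (10 of 17 higher, Tlr7 and Ccr9, adjusted p = 0.056 with an estimated correlation) and stromal genes (11 of 17 lower, adjusted p = 0.087 with an estimated correlation). Megakaryocyte genes (8 of 12 higher, Pf4 and Vwf) and ribosome genes (10 of 18 lower) were lost at adjusted p = 0.37 and adjusted p = 0.21 with an estimated correlation. NRF2, glycolysis and stress response genes (9 of 17, 11 of 18 and 11 of 20 higher) were each lost at adjusted p = 0.19 with an estimated correlation. Interferon-stimulated genes (8 of 19 lower, Rsad2 and Oas3) were lost at adjusted p = 0.54 with an estimated correlation. The interferon call also ended without unstimulated array 2 (adjusted p 0.0547), and the stress response call without any of 3 arrays (adjusted p up to 0.0759, without Flt3-L 48 h array 3). With a filter on dim genes those calls and the megakaryocyte, stromal and NRF2 calls ended. In counts adjusted over the list alone, 16 T and NK cell, 16 erythroid, 16 cholesterol, 9 megakaryocyte, 11 ribosome, 10 NRF2 and 12 glycolysis genes passed in the direction named, and in the other lists as many as over all genes. Against the direction named, 4 NRF2, 3 stress response, 2 T and NK cell, 2 interferon and 2 ribosome genes were called, and 1 each of the monocyte and macrophage, plasmacytoid, megakaryocyte, stromal and lysosome genes. There were 3682 genes higher and 3707 lower, 457 and 604 of them beyond 2-fold, and 3965 higher and 3786 lower when the arrays were quantile normalised again.

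After 11 days red cell, neutrophil and granule genes lay far below unstimulated cells. The red cell genes Car1, Rhag and Alas2 were 149-fold, 143-fold and 62.4-fold lower, the neutrophil genes Chil3 and Ly6g 109-fold and 85.2-fold, and the myeloperoxidase gene Mpo 68.3-fold. Rhag and Chil3 ended at mean log2 signals of 4.53 and 5.04, where background, not measured here, limits the fold. Progenitor genes fell as well, with Myb 20.8-fold lower (-4.38 ± 0.05), while the dendritic cell genes Itgax and Xcr1 were 15.2-fold and 17.1-fold higher. Called lists that held with an estimated correlation were lower progenitor (15 of 18), primary granule (12 of 12), late neutrophil (18 of 19), T and NK cell (15 of 19), erythroid (15 of 16), mast cell, basophil and eosinophil (12 of 16), G1 and S phase (22 of 25) and G2 and M phase genes (20 of 20). Higher lists that held were monocyte and macrophage (18 of 22), conventional dendritic cell (23 of 24) and lysosome genes (17 of 17). Adjusted over the list alone the counts were the same, except 16 of 16 erythroid genes. B lineage genes (16 of 19 lower, Igll1 and Ebf1) were lost at adjusted p = 0.086 with an estimated correlation, and cholesterol genes (16 of 17 higher) at adjusted p = 0.076 with an estimated correlation. Stromal genes (13 of 17 lower, Cxcl12 and Pecam1) were lost at adjusted p = 0.13 and megakaryocyte genes (8 of 12 lower) at adjusted p = 0.32 with an estimated correlation. Glycolysis genes (12 of 18 higher, P4ha1 and Slc2a1) and ribosome genes (9 of 18 lower) were lost at adjusted p = 0.36 with an estimated correlation. The p53 targets (12 of 18 higher, Phlda3 and Zmat3) were lost at adjusted p = 0.32 with an estimated correlation, and interferon genes (9 of 19 lower) at adjusted p = 0.6 with an estimated correlation. Leaving out 1 array ended the interferon call for 3 arrays (adjusted p up to 0.0965, without Flt3-L array 1), the p53 call for 2 (up to 0.0652, without Flt3-L array 3) and the ribosome call for 2 (up to 0.0727, without unstimulated array 3). Those calls and the glycolysis call also ended when the arrays were quantile normalised again. The interferon, p53 and ribosome calls ended with a filter on dim genes, and the p53 call with each array's median subtracted, with array weights and with a replicate block. When adjusted over the list alone, 10 interferon genes were lower and the other counts were the same. Opposite calls were 4 for p53, 3 each for progenitor, monocyte and macrophage, interferon and ribosome, 2 each for B lineage, T and NK cell, megakaryocyte, stromal, G1 and S phase and glycolysis, and 1 each for late neutrophil and mast cell genes. Calls numbered 5416 higher and 4935 lower, with 1359 and 1417 beyond 2-fold.

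Against unstimulated cells at 12 h, the lists not called had median changes of progenitor -0.03, primary granule -0.28, late neutrophil -0.02, conventional dendritic cell 0.11, plasmacytoid dendritic cell 0.11, B lineage 0.03, mast cell -0.04 and calcineurin and NFAT pathway 0.02. The remaining medians were NFAT-induced -0.04, CDK inhibitor -0.0022, p53 0.17, interferon -0.02, inflammatory -0.08, stress response 0.08, glycolysis 0.05 and transcription factor 0.11. Against unstimulated cells at 24 h, the lists not called had median changes of progenitor -0.05, late neutrophil 0.06, B lineage 0.14, megakaryocyte 0.0034, calcineurin and NFAT pathway 0.04 and NFAT-induced -0.0035. The other medians were CDK inhibitor 0.01, interferon -0.07, inflammatory 0.04, stress response 0.05 and transcription factor 0.15. Against unstimulated cells at 48 h, the lists not called had median changes of progenitor -0.05, late neutrophil -0.11, B lineage -0.29, calcineurin and NFAT pathway 0.03 and NFAT-induced 0.05. Further medians were p53 0.29, inflammatory 0.08, cytokine receptor 0.13 and transcription factor 0.09. Against unstimulated cells at 11 days, the lists not called had median changes of plasmacytoid dendritic cell -0.20, calcineurin and NFAT pathway -0.08, NFAT-induced 0.02, CDK inhibitor -0.64 and inflammatory 0.39. The rest had medians of stress response 0.12, NRF2 0.15, cytokine receptor -0.17 and transcription factor -0.27. Among these, the test and the median or mean differed in sign for the late neutrophil, B lineage, interferon and transcription factor lists at 12 h; the B lineage, megakaryocyte, CDK inhibitor and inflammatory lists at 24 h; the NFAT-induced and inflammatory lists at 48 h; the calcineurin and NFAT pathway, inflammatory and cytokine receptor lists at 11 days.

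**Figure D1:**
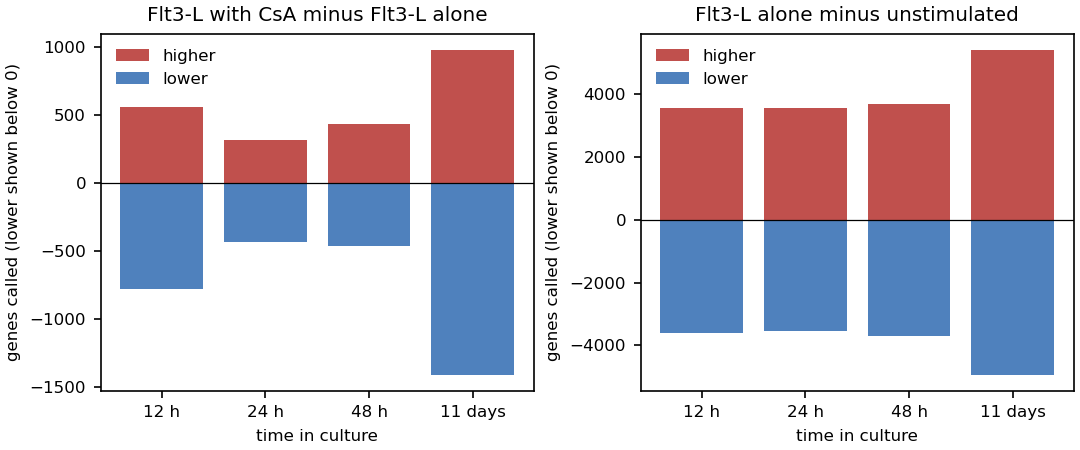
Genes called higher (above 0) and lower (below 0) at each time in culture, for CsA against Flt3-L alone and for Flt3-L against unstimulated cells. CsA calls were 318 higher and 436 lower at 24 h and 980 higher and 1411 lower at 11 days.

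The first CsA question was what CsA changed within 12 h of Flt3-L. The adhesion gene Jaml was 2.53-fold lower with CsA (-1.34 ± 0.12), Clec4n 2.44-fold (-1.29 ± 0.13) and fibronectin (Fn1) 2.07-fold (-1.05 ± 0.11). The cytokine gene Il1b was 1.85-fold lower (adjusted p 0.0079). Genes that NFAT commonly induces fell in 4 of 19 cases (5 adjusted over the list alone), namely Egr2 (-0.66 ± 0.10), Tnf (-0.56 ± 0.09), Nr4a1 (-0.40 ± 0.07) and the chemokine Ccl3 (-0.39 ± 0.07). Against these falls, stress response genes rose in 9 of 20 cases (13 adjusted over the list alone, median 0.21). The chaperone cofactor Dnajb9 was 1.51-fold higher, the transcription factor Ddit3 1.49-fold and Sesn2 1.34-fold, and among genes of transport out of the endoplasmic reticulum Sec24d was 1.73-fold and Bet1 1.65-fold higher. Cholesterol synthesis genes rose in 11 of 17 cases (14 adjusted over the list alone, median 0.25), Nsdhl by 0.30 ± 0.06 among them. These 3 lists held with an estimated correlation. Erythroid genes were called higher as a list with no single member called (median 0.17), and that call was lost at adjusted p = 0.25 with an estimated correlation. G2 and M phase genes rose in 4 of 20 cases (13 adjusted over the list alone, Cenpe among them), and G1 and S phase genes in 3 of 25 (3 higher and 1 lower adjusted over the list alone). Those cell cycle calls were lost at adjusted p = 0.2 and adjusted p = 0.42 with an estimated correlation. Monocyte and macrophage genes fell in 5 of 22 cases (9 adjusted over the list alone, Cd14 at -0.75 ± 0.11 and Adgre1 at -0.64 ± 0.06). Conventional dendritic cell genes fell in 6 of 24 with 1 higher (8 and 1 adjusted over the list alone, H2-Eb1 and H2-Aa), and B lineage genes in 4 of 19 (5 adjusted over the list alone, Fcmr and Cd72). Each of these 3 calls was lost at adjusted p = 0.42 with an estimated correlation, and each was also lost without CsA array 3, with adjusted p of 0.319, 0.0938 and 0.073, and with array weights. The G1 and S phase call was lost when the arrays were quantile normalised again. The remaining 19 lists were not called, with medians from -0.17 for interferon-stimulated genes to 0.06 for p53 targets and CDK inhibitors. Among them, the test and the median or mean differed in sign for the T and NK cell, calcineurin and NFAT pathway, NRF2, lysosome and ribosome lists.

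In the CsA effect at 12 h, 562 genes were called higher and 779 lower by limma, with 0 and 5 beyond 2-fold. Subtracting each array's median turned the split into 1052 higher and 323 lower, so at 12 h the balance of higher and lower genes depended on the normalization. The count rested on single arrays: it was 594, 664 and 473 without Flt3-L arrays 1, 2 and 3, and 451, 332 and 3221 without CsA arrays 1, 2 and 3. It was 177 in a fit of only the groups compared and 5301 with array weights. Of 46 named genes called, 14 lost their call when 1 of the 6 arrays was left out, Cd86, Bub1, Rag1, Ccne2, E2f3, Clec10a and Cenpe among them. Ccl3 and Nsdhl kept theirs, but not in a fit of only the groups compared.

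At 24 h the question was which of these effects persisted. Among genes of eosinophils and basophils, Epx was 2.59-fold lower with CsA (-1.37 ± 0.12), Mcpt8 2.47-fold (-1.31 ± 0.16) and the ribonuclease Ear6 2.41-fold (-1.27 ± 0.13). As a list, mast cell, basophil and eosinophil genes fell in 9 of 16 cases (12 adjusted over the list alone, median -0.48), with the receptors Il5ra and Ccr3 1.98-fold and 1.96-fold lower. B lineage genes fell in 8 of 19 cases (12 adjusted over the list alone, median -0.37), Fcmr 2.2-fold, Bank1 1.74-fold and Fcrla 1.72-fold, and the chemokine receptor Cxcr5 was 2.65-fold lower. Il1b was 3.6-fold (-1.85 ± 0.19) and Cd101 3.67-fold lower. NFAT-induced genes fell in 5 of 19 cases (6 adjusted over the list alone), with Ptgs2 at -0.80 ± 0.15, Egr2 at -0.60 ± 0.10 and Ccl4 at -0.43 ± 0.07. Stress response genes rose in 9 of 20 cases (14 adjusted over the list alone, median 0.28), led by Trib3 at 0.80 ± 0.11 and Dnajb9 at 0.65 ± 0.07, and their regulator Atf5 was 1.8-fold higher. Cholesterol synthesis genes rose in 12 of 17 cases (16 adjusted over the list alone, median 0.32), with Lss at 0.49 ± 0.07, Fdft1 at 0.40 ± 0.06 and Nsdhl at 0.40 ± 0.06. These 5 lists held with an estimated correlation. The kallikrein gene Klk1b11, already 1.99-fold higher with CsA at 12 h, was 2.63-fold higher at 24 h (1.40 ± 0.11).

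Other lists called at 24 h did not hold. Conventional dendritic cell genes fell in 8 of 24 cases (9 lower and 2 higher adjusted over the list alone, Ccl22 and H2-Oa) and p53 targets rose in 3 of 18 (3 higher and 1 lower adjusted over the list alone, Sesn2 and Aen), both at adjusted p = 0.21 with an estimated correlation. Plasmacytoid dendritic cell genes were called lower with no member called, also at adjusted p = 0.21 with an estimated correlation. Erythroid genes rose in 2 of 16 cases (4 adjusted over the list alone, Rhag) and G2 and M phase genes in 1 of 20 (12 adjusted over the list alone, Cenpe). Myeloid and dendritic cell transcription factors fell in 3 of 26 (4 adjusted over the list alone, Egr2 and Irf4). All of these had adjusted p = 0.08 with an estimated correlation. The G1 and S phase and ribosome lists were called higher with no member called, at adjusted p = 0.3 with an estimated correlation. Inflammatory genes fell in 5 of 21 cases (5 adjusted over the list alone, Il1b and Il1rn), at adjusted p = 0.19 with an estimated correlation, and NRF2 genes rose in 1 of 17 (5 adjusted over the list alone, Srxn1), at adjusted p = 0.11 with an estimated correlation. Cytokine receptor and STAT response genes fell in 3 of 21 cases (6 lower and 3 higher adjusted over the list alone, Csf3r and Mcl1), at adjusted p = 0.24 with an estimated correlation. Late neutrophil genes fell in 3 of 19 (4 adjusted over the list alone, Ly6g, Cxcr2 and Csf3r), at adjusted p = 0.55 with an estimated correlation. Leaving out 1 array ended 5 of the list calls. The late neutrophil call ended for 3 arrays (adjusted p up to 0.118, without Flt3-L array 2), the ribosome call for 2 (up to 0.111, without Flt3-L array 1) and the cytokine receptor call for 2 (up to 0.08, without CsA array 1). The plasmacytoid call ended without CsA array 2 (0.0569) and the p53 call without CsA array 3 (0.133). In a fit of only the groups compared the cytokine receptor call ended as well, and with a filter on dim genes the late neutrophil call. The 11 other lists were not called, and the test and the median or mean differed in sign for the progenitor, calcineurin and NFAT pathway, CDK inhibitor, glycolysis and lysosome lists. In the CsA effect at 24 h, 318 genes were higher and 436 lower, 1 and 17 of them beyond 2-fold, and without CsA array 1, 309 were higher and 285 lower. The total of 754 fell to 475 without Flt3-L array 1 and to 396 in a fit of only the groups compared, and 10 of 52 named genes lost their call without 1 array, Rag1, Ddit3, Aen, Irf4, Cenpe and Rhag among them.

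At 48 h the eotaxin receptor Ccr3 was 4.01-fold lower (-2.00 ± 0.13), the lipoxygenase Alox15 4-fold (-2.00 ± 0.12) and the receptor gene Adgre4 3.52-fold (-1.82 ± 0.13). Mast cell, basophil and eosinophil genes fell in 11 of 16 cases (13 adjusted over the list alone, median -0.49), and B lineage genes in 14 of 19 (15 adjusted over the list alone, median -0.53), with Fcrla at -1.24 ± 0.15, Ebf1 at -0.80 ± 0.14 and Rag1 at -0.82 ± 0.14. Plasmacytoid dendritic cell genes fell in 4 of 17 (8 adjusted over the list alone). Myeloid and dendritic cell transcription factors fell in 4 of 26 with 1 higher (8 and 1 adjusted over the list alone), Egr2 and Irf4 leading. NFAT-induced genes again fell in 4 of 19 (7 adjusted over the list alone), Ptgs2 2.07-fold, Egr2 1.51-fold and Nr4a1 1.4-fold. Stress response genes rose in 8 of 20 cases (15 adjusted over the list alone, median 0.27), with Trib3 1.85-fold, Dnajb9 1.62-fold and asparagine synthetase (Asns) 1.55-fold higher, and Atf5 1.95-fold. Those 6 lists held with an estimated correlation. The monocyte chemoattractants Ccl2 and Ccl7 rose 1.99-fold (0.99 ± 0.12) and 1.97-fold (0.98 ± 0.14) while Il1b was 3.32-fold lower, so inflammatory genes moved both ways, 2 higher and 5 lower of 21 (2 and 5 adjusted over the list alone). That list was called lower and lost at adjusted p = 0.22 with an estimated correlation. Monocyte and macrophage genes fell in 5 of 22 with 1 higher (7 and 1 adjusted over the list alone, Cd14, F13a1 and Cx3cr1), at adjusted p = 0.14 with an estimated correlation. Conventional dendritic cell genes fell in 4 of 24 with 1 higher (5 and 1 adjusted over the list alone, Ccl22 and Cd209a), at adjusted p = 0.18 with an estimated correlation. Cholesterol synthesis genes rose in 3 of 17 (4 adjusted over the list alone, Insig1), at adjusted p = 0.19 with an estimated correlation, and ribosome genes in 5 of 18 (6 adjusted over the list alone, Rrp12 and Utp20), at adjusted p = 0.1 with an estimated correlation. Late neutrophil genes (3 of 19 lower, 4 adjusted over the list alone, Ly6g), interferon-stimulated genes (1 of 19 lower, 2 lower and 1 higher adjusted over the list alone, Cxcl10) and erythroid genes (1 of 16 higher, 1 adjusted over the list alone, Slc4a1) were lost at adjusted p = 0.39, adjusted p = 0.58 and adjusted p = 0.32 with an estimated correlation. The late neutrophil and interferon calls also ended without CsA array 1, each at an adjusted p of 0.402 and with medians of 0.02 and 0.01. The late neutrophil call ended without 1 other array too, and the erythroid call without CsA array 3, at 0.0774. The 14 other lists were not called, and the test and the median or mean differed in sign for the progenitor, CDK inhibitor and lysosome lists. In the CsA effect at 48 h, 432 genes were higher and 467 lower, 1 and 23 beyond 2-fold, and with a filter on dim genes 572 were higher and 554 lower. The total of 899 became 586 without CsA array 1 and 451 in a fit of only the groups compared, and 12 of 56 named genes lost their call without 1 array, Cxcr2, Csf3r, Tnf, Cd83, Insig1 and Lss among them. Rrp12, Utp20 and Slc4a1 lost theirs in the fit of only the groups compared.

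The comparison at 11 days asked how cultures kept with Flt3-L and CsA differed from those kept with Flt3-L alone. The B cell genes Cd79b and Cd79a were 5.09-fold (-2.35 ± 0.10) and 4.94-fold lower (-2.30 ± 0.10). Ms4a1 was 9.92-fold lower (-3.31 ± 0.15), with log2 signals of 4.98 to 5.25 in the CsA arrays, where background, not measured here, limits the fold. As a list, 11 of 19 B lineage genes were lower and 1 higher (the same counts adjusted over the list alone, median -0.48), a call lost at adjusted p = 0.064 with an estimated correlation. Late neutrophil genes fell in 12 of 19 cases with 1 higher (13 and 2 adjusted over the list alone, median -1.04), Ngp 4.36-fold, Lcn2 3.93-fold and S100a8 3.85-fold. In the CsA arrays S100a8 lay at log2 signals of 5.69 to 6.30 and Cd79a at 6.10 to 6.36. These are below the arrays' medians, so background may limit those folds too. Conventional dendritic cell genes fell in 21 of 24 cases (21 adjusted over the list alone, median -0.53), with the cross-presenting subset genes Clec9a and Xcr1 3.09-fold and 2.81-fold lower and Itgax 2.3-fold lower. Monocyte and macrophage genes showed no such shift, with 2 higher and 4 lower of 22, a median of 0.09 and a mean of -0.03. Oxidative stress genes of the NRF2 list fell in 10 of 17 with 2 higher (14 and 2 adjusted over the list alone), Slc7a11 2.61-fold, Nqo1 2.25-fold and Srxn1 1.89-fold. Myeloid and dendritic cell transcription factors fell in 10 of 26 with 1 higher (14 and 1 adjusted over the list alone), Spib 3-fold, Egr2 2-fold and Irf4 1.92-fold. That list is not separate from the others. Spib and Tcf4 are also in the plasmacytoid list, and Batf3 and Zbtb46 in the conventional dendritic cell list. Mast cell, basophil and eosinophil genes fell in 8 of 16 (8 adjusted over the list alone), Ccr3 3.92-fold. Rises were led by the channel gene Mcoln3 (4.37-fold, 2.13 ± 0.10), the crosslinking enzyme Lox (4.19-fold, 2.07 ± 0.13) and the receptor Gprc5b (3.17-fold, 1.67 ± 0.10). The late neutrophil, conventional dendritic cell, NRF2, transcription factor and mast cell lists held with an estimated correlation.

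Also lost were the calls for progenitor markers (7 of 18 lower and 2 higher, 7 and 3 adjusted over the list alone, Procr, Cd34 and Kit) and for cholesterol synthesis genes (9 of 17 lower, 10 adjusted over the list alone, Fdft1, Cyp51 and Sqle), each at adjusted p = 0.064 with an estimated correlation. Plasmacytoid dendritic cell genes moved both ways, 9 lower and 4 higher of 17 (the same adjusted over the list alone), with Ly6d 2.53-fold lower and Cox6a2 3.09-fold higher, and the lower call was lost at adjusted p = 0.085 with an estimated correlation. The p53 targets fell in 7 of 18 with 2 higher (9 and 2 adjusted over the list alone, Btg2 and Phlda3), at adjusted p = 0.066 with an estimated correlation, and primary granule genes in 4 of 12 (5 adjusted over the list alone, Nkg7 and Serpinb1a), at adjusted p = 0.14 with an estimated correlation. Stress response genes rose in 6 of 20 (6 higher and 2 lower adjusted over the list alone, Asns 2.13-fold, Chac1 1.87-fold, Trib3 1.77-fold), at adjusted p = 0.17 with an estimated correlation. T and NK cell genes fell in 6 of 19 with 2 higher (6 and 2 adjusted over the list alone), Cd3g and Il2rb falling while Cd28 was 2.04-fold higher, at adjusted p = 0.22 with an estimated correlation. Megakaryocyte genes (3 of 12 lower, 3 adjusted over the list alone, F2rl2 and Ppbp) and interferon-stimulated genes (6 of 19 lower, 6 adjusted over the list alone, Mx1 and Usp18) were lost at adjusted p = 0.37 and adjusted p = 0.5 with an estimated correlation. Without CsA array 1 the T and NK cell adjusted p was 0.0557, and without Flt3-L array 3 the interferon adjusted p was 0.0696 and the median -0.00890. The 13 other lists were not called. Of these, the monocyte and macrophage, CDK inhibitor, inflammatory and lysosome lists differed in sign between the test and the median or mean. The stress response call ended in a fit of only the groups compared, and the T and NK cell and megakaryocyte calls with a filter on dim genes. In the CsA effect at 11 days, 980 genes were higher and 1411 lower, 24 and 150 beyond 2-fold, and leaving out any 1 of the 6 arrays left between 1844 and 2196 calls. Only 4 of 76 named genes called, Nfatc1, Ppp3cb, Mpo and Ctsg, lost their call without 1 array.

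**Figure D2:**
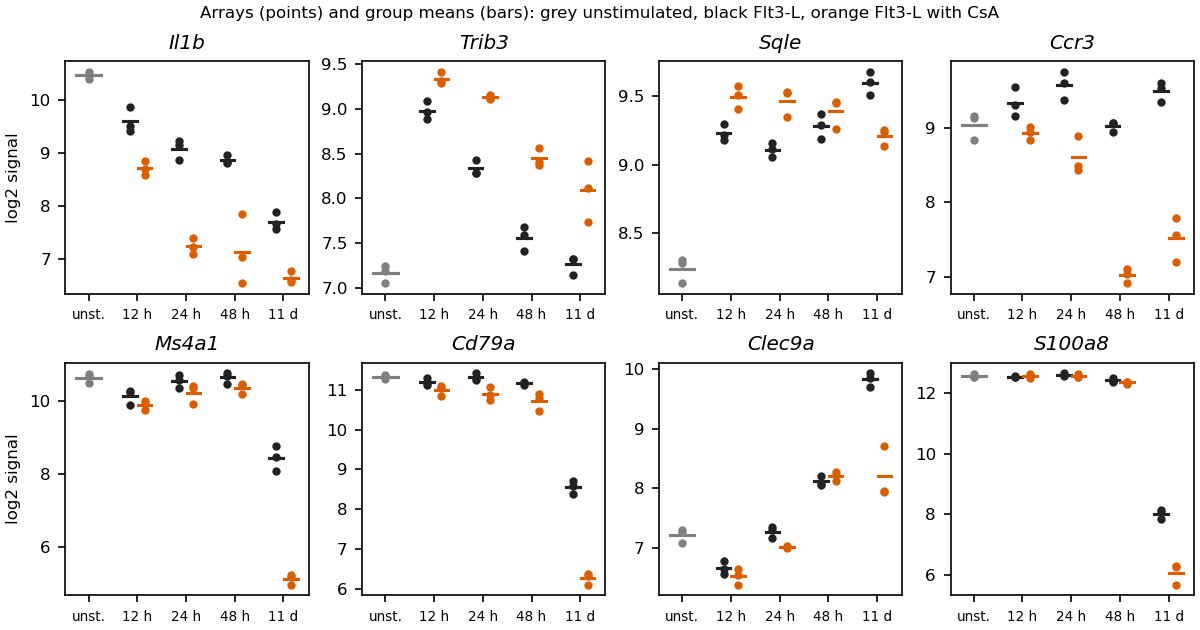
Log2 signal of 8 genes by group, with single arrays as points and group means as bars, for unstimulated cells and for cells with Flt3-L alone or with CsA at each time. Il1b lay lower with CsA at every time, from 1.85-fold at 12 h to 3.6-fold at 24 h, while Ms4a1 at 11 days lay at log2 signals of 4.98 to 5.25 with CsA.

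Of 16 calcineurin and NFAT pathway genes, 1, 2, 2 and 3 were called with CsA in order of time, where 6.73%, 3.78%, 4.51% and 12.0% of all genes were called. The mean effect called Ppp3cb and Cabin1 higher and Nfatc1, Nfatc2, Nfat5 and Rcan1 lower, 6 of the 16 against 16.0% of all genes. The NFAT gene Nfatc1, which NFAT proteins induce in a feedback loop, was lower with CsA at 12 h (-0.22 ± 0.06), 24 h (-0.29 ± 0.06), 48 h (-0.31 ± 0.06) and 11 days (-0.21 ± 0.06), with limma adjusted p of 0.023, 0.0025, 0.0011 and 0.014. The 12 h call ended for 5 of the 6 arrays left out 1 at a time (adjusted p up to 0.0734, without Flt3-L array 2), and the 11 day call for 3 (up to 0.097, without Flt3-L array 3). In fits of only the groups compared Nfatc1 was not called at 12 h, 24 h or 11 days. The calcineurin inhibitor gene Rcan1, another feedback target, was lower at 11 days only (-0.63 ± 0.09, adjusted p 1.5e-05). At 12, 24 and 48 h its adjusted p was 0.39, 0.82 and 0.7. Cabin1 was called higher at 24 h and Nfat5 lower at 48 h. Nfatc2, Nfatc3, Nfatc4 and the calcineurin gene Ppp3ca were not called at any single time, and Ppp3cb was called at 11 days (0.18 ± 0.05), a call that ended without either of 2 arrays (adjusted p up to 0.0896, without CsA array 2). The list of pathway components was not called by camera at any time, with medians of -0.02, 0.01, -0.03 and -0.01 in order of time. By fry, which compares a list with no other genes, PValue called it at 48 h and 11 days (adjusted p 0.0066 and 0.012) and in the mean effect (adjusted p 0.00039), and PValue.Mixed called it at all 4 times. CDK4 with its D cyclins gates entry into S phase. Cdk4, Cdk6 and Ccnd1 were not called at any time. Some alternatives called them, Ccnd1 lower at 12 h and higher at 48 h with a trended and robust variance or with a filter on dim genes, Cdk4 higher at 48 h with that variance and Cdk6 lower at 12 h with array weights. Array weights also called Nfatc4 lower at 12 h, and the filter on dim genes Nfatc2 lower at 11 days. Among the D cyclins, Ccnd2 (-0.39 ± 0.07) and Ccnd3 (-0.26 ± 0.06) were lower at 11 days. The lists of CDK inhibitors with pocket proteins, of G1 and S phase genes and of G2 and M phase genes were not called at 48 h or 11 days.

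CsA effects at different times shared no arrays, but their tests shared each gene's variance estimate from the 1 model. That can raise the number of shared calls above the count for independent lists. Between 24 h and 48 h, 184 genes were called higher and 266 lower at both, where independent lists would share 6.89 and 10.2, none were called in opposite directions, and the changes correlated at 0.66. This correlation, like the others, is across genes, which are not independent replicates. Between 12 h and 24 h, 163 higher and 139 lower calls were shared (8.96 and 17 for independent lists, correlation 0.43), with 1 and 1 opposite. Between 12 h and 48 h they were 142 and 132 (12.2 and 18.2, correlation 0.27), with 1 and 3 opposite. Between 48 h and 11 days 124 higher and 200 lower calls were shared (21.2 and 33.1, correlation 0.27), with 25 and 20 genes called in opposite directions. Between 24 h and 11 days the shared calls were 79 and 182 (15.6 and 30.9, correlation 0.20), with 32 and 21 opposite. The 12 h and 11 day changes had a correlation of -0.0018, with 86 higher and 117 lower calls shared (27.6 and 55.1 for independent lists) and 35 and 32 opposite. At all 4 times 30 genes were higher, including the stress regulators Atf4, Atf5 and Trib3, and 54 were lower, including Il1b, Fn1, Egr2, Nr4a1, Jaml, Cxcr5 and Irf4. Atf4, Cxcr5 and the count of 90 genes called at all times were looked up after the values were seen.

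Averaged over the 4 times, the largest falls were those of Il1b (2.61-fold, -1.38 ± 0.10), Ccr3 (2.53-fold) and Fcmr (2.5-fold), followed by Fn1 and Jaml. The largest rises were Klk1b11 (2.22-fold, 1.15 ± 0.05), Mcoln3 (1.86-fold), Atf5 (1.65-fold) and Trib3 (1.64-fold), followed by Arfgef3. Stress response genes were higher in 17 of 20 cases (17 adjusted over the list alone). Lower were 15 of 19 B lineage genes, 12 of 16 mast cell, basophil and eosinophil genes, 10 of 19 NFAT-induced genes and 12 of 19 late neutrophil genes. Lower too were 20 of 24 conventional dendritic cell genes, 11 of 17 plasmacytoid dendritic cell genes and 10 of 26 myeloid and dendritic cell transcription factors. In counts adjusted over the list alone, the lower counts were the same, except 12 transcription factors. These 8 of 18 called lists held with an estimated correlation. Called and lost were lower megakaryocyte (3 of 12, adjusted p = 0.39 with an estimated correlation) and inflammatory genes (7 of 21, adjusted p = 0.24 with an estimated correlation) and lower monocyte and macrophage genes (7 of 22, adjusted p = 0.3 with an estimated correlation), whose median was 0.00257 and whose mean was -0.10. Interferon-stimulated genes (10 of 19 lower, adjusted p = 0.3 with an estimated correlation) and cytokine receptor genes (8 of 21 lower, adjusted p = 0.085 with an estimated correlation) were lost as well. The same applied to higher erythroid (8 of 16, adjusted p = 0.18 with an estimated correlation), G1 and S phase (9 of 25, adjusted p = 0.3 with an estimated correlation), G2 and M phase (11 of 20, adjusted p = 0.16 with an estimated correlation), cholesterol (9 of 17, adjusted p = 0.08 with an estimated correlation) and ribosome genes (4 of 18, adjusted p = 0.3 with an estimated correlation). Adjusted over the list alone, 4 megakaryocyte, 7 inflammatory, 9 monocyte and macrophage, 14 interferon, 12 cytokine receptor, 11 erythroid, 12 G1 and S phase, 16 G2 and M phase, 13 cholesterol and 4 ribosome genes passed in those directions. The megakaryocyte call ended for 4 of 24 arrays left out 1 at a time (adjusted p up to 0.101, without Flt3-L 48 h array 3) and with a filter on dim genes. Members called against the direction of their list were 3 inflammatory, 2 monocyte and macrophage, 2 cytokine receptor and 2 G1 and S phase genes, and 1 each of the conventional dendritic cell, plasmacytoid dendritic cell and interferon genes. In total 1547 genes were higher and 1639 lower. With each array's median subtracted 1826 were higher and 1383 lower, and without the arrays numbered 2, a fit chosen after the data were seen, 641 and 1125, so the balance depended on normalization and arrays.

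The CsA effect was then tested for a change with time. An F test of the 4 effects called 1957 genes, and the effect at 11 days differed from the mean of the 3 earlier effects in 2374 genes, 1039 with a more positive and 1335 with a more negative effect. Among the most negative shifts were those of Serpinb9b (-3.07 ± 0.11), Ngp (-2.20 ± 0.14), the collagenase Mmp13 (-2.18 ± 0.14) and Ly6a2 (-2.13 ± 0.13). That of Ms4a1 (-3.02 ± 0.17) is limited by background, through its low signal with CsA at 11 days. The most positive were those of Lox (1.95 ± 0.15), Mcoln3 (1.65 ± 0.12), Gprc5b (1.58 ± 0.12), Cox6a2 (1.37 ± 0.17) and the desaturase Scd1 (1.34 ± 0.12). Cholesterol synthesis genes, higher with CsA at 12 h and 24 h, had a more negative effect at 11 days in 15 of 17 cases (16 adjusted over the list alone, median -0.40). NRF2 genes did so in 10 of 17 (12 adjusted over the list alone). Late neutrophil genes did so in 13 of 19 and conventional dendritic cell genes in 15 of 24 (13 and 16 adjusted over the list alone). The p53 targets did so in 9 of 18 and myeloid and dendritic cell transcription factors in 8 of 26 (10 and 12 adjusted over the list alone). These 6 of 13 called lists held with an estimated correlation. As examples, without CsA Clec9a lay at log2 signals of 6.56 to 7.34 at 12 h and 24 h and at 9.70 to 9.93 at 11 days. S100a8 lay at 12.53 to 12.65 and at 7.86 to 8.13. The difference thus compares CsA effects at unlike signal levels, and background, not measured here, may limit early falls of dim genes. Lost were progenitor markers (6 of 18, adjusted p = 0.062 with an estimated correlation), stress response genes (8 of 20, adjusted p = 0.18 with an estimated correlation), primary granule genes (3 of 12) and erythroid genes (6 of 16), the latter pair at adjusted p = 0.28 with an estimated correlation. When adjusted over the list alone, their counts were 6, 8, 4 and 7. Also lost were B lineage (5 of 19, 8 adjusted over the list alone) and glycolysis genes (4 of 18, 4 adjusted over the list alone), each at adjusted p = 0.58 with an estimated correlation, and ribosome genes with no member called, at adjusted p = 0.41 with an estimated correlation. The stress response call ended without CsA 11 day array 1 (adjusted p 0.0823) and the glycolysis call for 5 of 24 arrays (up to 0.0755, without Flt3-L 11 day array 3). Those calls and the ribosome call also ended when the arrays were quantile normalised again, and with a filter on dim genes, and the glycolysis call with array weights (adjusted p 0.0520). In the other direction, 3 B lineage, 3 transcription factor, 2 stress response, 2 glycolysis, 1 progenitor, 1 late neutrophil and 1 erythroid gene were called. Without CsA 12 h array 3, 1488 genes had a more positive and 1466 a more negative effect. The F test called 3825 genes with array weights.

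With CsA at 12 h, the lists not called had median changes of progenitor 0.01, primary granule 0.05, late neutrophil 0.03, plasmacytoid dendritic cell -0.12, T and NK cell -0.04, megakaryocyte -0.12, mast cell -0.13, stromal -0.08, calcineurin and NFAT pathway -0.02 and CDK inhibitor 0.06. The remaining medians were p53 0.06, interferon -0.17, inflammatory -0.09, NRF2 -0.0049, glycolysis 0.02, lysosome 0.03, cytokine receptor -0.07, transcription factor -0.01 and ribosome -0.00073. With CsA at 24 h, the lists not called had median changes of progenitor 0.02, primary granule -0.06, monocyte and macrophage -0.05, T and NK cell -0.03, megakaryocyte 0.06 and stromal 0.03. The other medians were calcineurin and NFAT pathway 0.01, CDK inhibitor 0.00046, interferon -0.12, glycolysis 0.01 and lysosome 0.01. With CsA at 48 h, the lists not called had median changes of progenitor 0.02, primary granule -0.08, T and NK cell -0.03, megakaryocyte -0.06, stromal 0.03, calcineurin and NFAT pathway -0.03 and G1 and S phase 0.04. Further medians were G2 and M phase -0.01, CDK inhibitor -0.0028, p53 0.07, NRF2 0.12, glycolysis 0.05, lysosome 0.03 and cytokine receptor -0.02. With CsA at 11 days, the lists not called had median changes of monocyte and macrophage 0.09, erythroid -0.01, stromal 0.09, calcineurin and NFAT pathway -0.01, NFAT-induced -0.01, G1 and S phase 0.07 and G2 and M phase 0.07. The rest had medians of CDK inhibitor -0.03, inflammatory 0.03, glycolysis -0.05, lysosome 0.04, cytokine receptor -0.03 and ribosome -0.02. For the mean CsA effect the lists not called had median changes of progenitor -0.04, primary granule -0.05, T and NK cell -0.10, stromal -0.01 and calcineurin and NFAT pathway -0.02. The remaining medians were CDK inhibitor -0.01, p53 0.00097, NRF2 -0.07, glycolysis 0.0022 and lysosome 0.04. For the difference between 11 days and the earlier times the lists not called had median changes of monocyte and macrophage 0.16, plasmacytoid dendritic cell -0.01, T and NK cell -0.05, megakaryocyte -0.04, mast cell -0.01, stromal 0.13, calcineurin and NFAT pathway -0.0044 and NFAT-induced 0.03. The other medians were G1 and S phase -0.01, G2 and M phase -0.04, CDK inhibitor -0.03, interferon -0.03, inflammatory 0.15, lysosome 0.06 and cytokine receptor 0.04. Signs of the test and of the median or mean differed among these for the stromal, CDK inhibitor, p53, glycolysis and lysosome lists in the mean effect, and for the CDK inhibitor, inflammatory, lysosome and cytokine receptor lists in the difference.

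**Figure D3:**
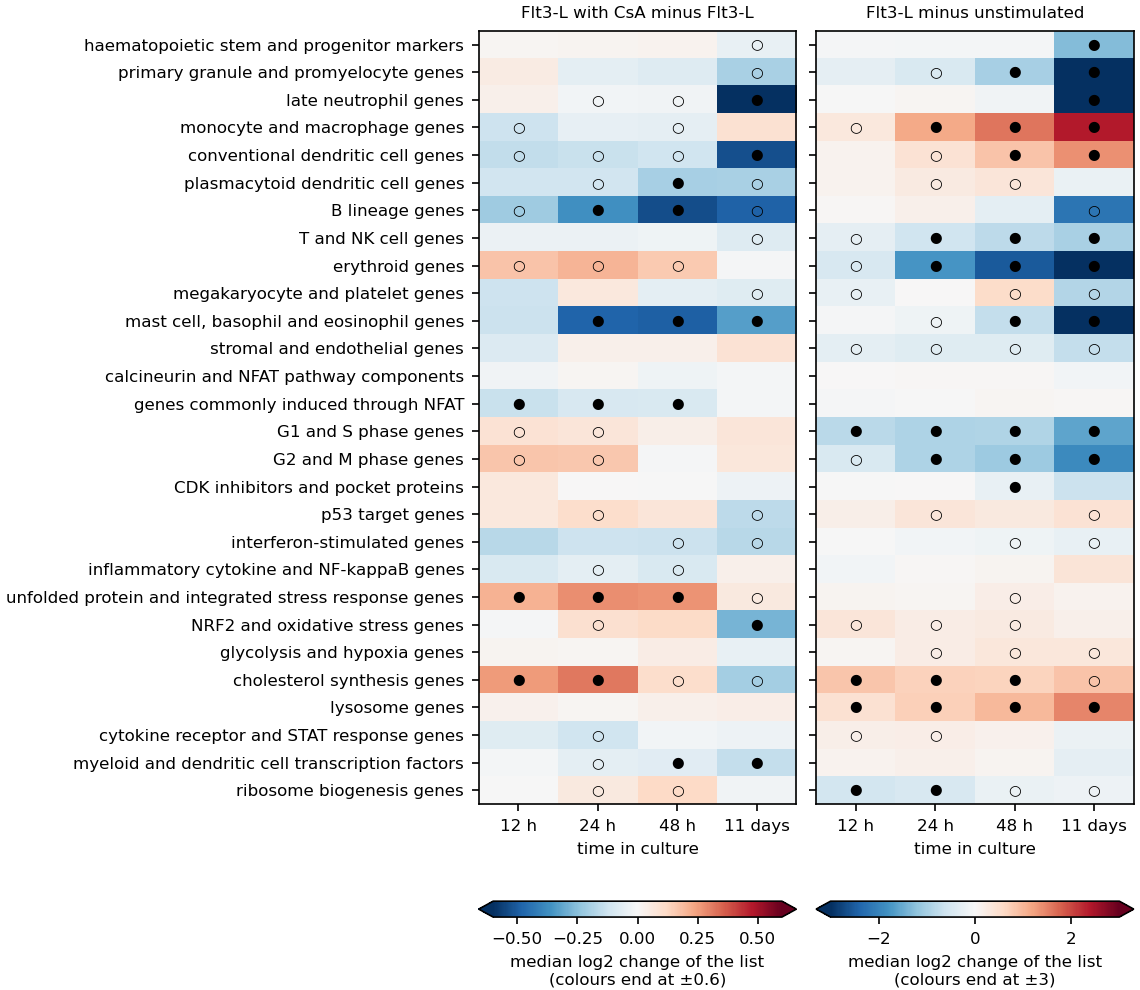
Median log2 change of each of the 28 gene lists at each time, for CsA against Flt3-L alone and for Flt3-L against unstimulated cells. Filled dots are lists called with both the preset and the estimated correlation, open dots those called with the preset correlation only, and the cholesterol list turns from a median of 0.32 at 24 h to -0.20 at 11 days, the latter with an open dot.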

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

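The tests of dilution by other cells below were written after the result was seen, as was the choice of the 3 patterns weighed.

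A difference between time points in the CsA effect singled out the following results, each by a test of the difference itself in limma. The F test called 1957 genes and the difference between 11 days and the earlier times 2374. Among genes the difference was -3.07 for Serpinb9b, -3.02 for Ms4a1 (limited by background at its low signal with CsA at 11 days), -2.20 for Ngp, -2.18 for Mmp13 and -2.13 for Ly6a2, and 1.95 for Lox, 1.65 for Mcoln3, 1.58 for Gprc5b, 1.37 for Cox6a2 and 1.34 for Scd1. Among lists, the median difference was -0.660 for late neutrophil, -0.399 for cholesterol, -0.368 for conventional dendritic cell, -0.338 for NRF2, -0.203 for transcription factor and -0.197 for p53 genes. It was -0.212 for erythroid, -0.120 for stress response, -0.119 for glycolysis, -0.108 for primary granule, -0.0795 for ribosome, -0.0715 for B lineage and -0.0488 for progenitor genes, whose calls were lost with an estimated correlation. Signal levels without CsA also changed between the early times and 11 days, as for Clec9a and S100a8 above. Of 100 splits of the arrays within each time, 1, the real one, reached the F test's count (highest other 1269). The same held for the difference's count (highest other 1584) and the mean effect's 3186 (highest other 447). A share of 1 in 100, the smallest possible here, argues against a chance division of the arrays. The splits mixed arrays with and without CsA and took no account of replicate numbers. They therefore test for any CsA effect and cannot decide whether the effects were equal over time. For comparisons of 3 against 3 arrays the 10 splits are too few for a share under 0.05. The real splits gave 1341, 754, 899 and 2391 genes for CsA at 12 h, 24 h, 48 h and 11 days, against 0, 1, 0 and 4 for the highest other, and for Flt3-L 7169, 7103, 7389 and 10351 against 0.

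The comparisons did not use 7035 probe sets without a single gene symbol. Of these, 56 were called with CsA at 12 h, 50 at 24 h, 41 at 48 h and 234 at 11 days. These were smaller shares than the 1341, 754, 899 and 2391 called of the 19935 genes tested. No explanation was tested for these.

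The third CsA array at 12 h lay closer to an array without CsA than to its own group. Over 450 genes called the same way at 24 h and 48 h, it was shifted by 0.244 in the direction of the CsA effect, against 0.261 and 0.218 for the other CsA arrays at 12 h, which argues against RNA of a culture without CsA. A swap is argued against by the arrays without CsA, whose largest shift was 0.0188. A handling difference of this array stays open and was not tested. The third CsA array at 24 h, which also lay closest to an array without CsA, was not checked for a wrong label or a swap.

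Cholesterol synthesis genes were higher with CsA at 12 h and 24 h and lower at 11 days, though the 11 day call was lost at adjusted p = 0.064 with an estimated correlation. A batch that the arrays numbered 1 shared equally would cancel in each CsA comparison, so leaving them out tests only one that struck them unequally, which the median difference of -0.403 without them argues against. A single array is argued against by the highest value over 24 left-out arrays, -0.359. The list's -0.399 lay below all of 10000 random lists of like signal, whose lowest was -0.199, against a general shift of such genes. The pattern may reflect a biological change with time in culture, a hypothesis found and tested on the same arrays, and a change in the cells present stays open.

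B lineage and mast cell, basophil and eosinophil genes were lower with CsA at 24 h and 48 h. Dilution by other cells would lower T and NK cell, megakaryocyte, stromal and erythroid genes alike. The median of those 4 lists together was 0.0122 at 48 h and 0.0629 at 24 h. These medians were known when the lists were chosen, so the comparison cannot decide on dilution. The difference of medians was -0.516 at 48 h (95% bootstrap interval -0.641 to -0.435) and -0.491 at 24 h (-0.593 to -0.335). It was taken over 35 and 64 genes, which are not independent replicates. Against all 10 other cell type lists (176 genes), those called lower included, it was -0.477 (-0.600 to -0.402) at 48 h and -0.417 (-0.509 to -0.273) at 24 h. Those lists include genes of cells that could do the diluting, so this comparison cannot decide either. Dim probe sets are argued against by the median of -0.606 at 48 h in members brighter than the median gene (22 of 25 called lower), and a single array by the highest median over left-out arrays, -0.382. Fewer cells of these types, or lower expression within them, could each give the pattern, and these were not tested.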

How the results depend on the processing

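The alternatives that leave out all arrays of a number were chosen after the data were seen. Fits with arrays left out pool the spread over the remaining groups. The number of genes called by the CsA effect at 12 h was 177 in a fit of only the groups compared, 5301 with array weights and 2111 with a replicate block, and the block changed no other count by more than 1.5 times. The block added a call for 14 named genes, ended 1 list call and called 16 lists for CsA at 48 h. With a filter on dim genes 20 list calls ended, which left 13 of the 15 calls for CsA at 11 days, 10 of 13 for the difference and 9, 15, 14 and 16 for Flt3-L. At 12 h each array's deviations correlated best with the array of its own number, at 0.19, 0.19 and 0.0979, a hint from the data only. For CsA at 11 days the values were 0.01, 0.11 and -0.04, and for Flt3-L 0.30, 0.02 and 0.18 at 48 h and 0.10, -0.05 and 0.21 at 11 days. With only the groups compared the counts were 396 for the CsA effect at 24 h and 451 for the CsA effect at 48 h, fits with fewer arrays. The F test, CsA effect by time, gave 3825 with array weights. Leaving out arrays gave 88 to 3221 genes for the CsA effect at 12 h, 169 to 594 at 24 h, 265 to 693 at 48 h and 1220 to 2196 at 11 days. It gave 1766 to 3373 for the mean CsA effect over 4 times, 939 to 2954 for the CsA effect at 11 days minus the mean of the earlier ones and 563 to 2918 for the F test. The lowest came without all arrays numbered 2 (12 h, mean) or 3 (the others). The highest in 12 h, mean, difference and F test came without CsA 12 h array 3. For Flt3-L the ranges were 4950 to 6622, 5291 to 6611, 5808 to 6894 and 9195 to 10059. Gene list tests with an estimated correlation called 3, 5, 6 and 5 lists for CsA in order of time, 8 for the mean, 6 for the difference and 4, 8, 11 and 11 for Flt3-L. By fry, PValue called 20 for Flt3-L at 12 h. PValue.Mixed called 22 for CsA at 12 h, 26 at 11 days, 28 for the mean, 25 for the difference and 28 for Flt3-L at 12 h and at 24 h. With arrays left out the lists called ranged over 6 to 12, 12 to 18, 13 to 16 and 15 to 17 for CsA, 16 to 20 for the mean, 12 to 16 for the difference, and 11 to 14, 16 to 18, 16 to 21 and 16 to 20 for Flt3-L. Signs turned only for genes that were not called. With each array's median subtracted, Ccnd3 became 0.0144 and Nfatc2 0.0172 at 12 h, and with array weights Nfatc3 became -0.0022 at 24 h. With arrays left out, the values ranged from -0.0886 to 0.0156 (Nfatc2, CsA effect at 12 h) and from -0.203 to 0.0266 (Rcan1, CsA effect at 12 h). The ranges were -0.0164 to 0.531 (Car1, CsA effect at 24 h), -0.0152 to 0.0344 (Ccnd3, CsA effect at 24 h), -0.0233 to 0.0315 (Cdk6, CsA effect at 24 h), -0.0275 to 0.0391 (Nfatc3, CsA effect at 24 h) and -0.0366 to 0.216 (Npm1, CsA effect at 24 h). Later ranges were -0.0283 to 0.146 (Nfatc4, CsA effect at 48 h), -0.0396 to 0.00582 (Ppp3cb, CsA effect at 48 h) and -0.0502 to 0.0364 (Nfatc3, CsA effect at 11 days). Across all named genes, an array left out ended the call in 266 fits, turned the sign in 19, added a call in 9 and left 5817 the same. A fit of only the groups compared ended 39 calls, added 4 and left 596 the same. Other than where fewer arrays entered a fit, the cause was not tested. Signal over background limits what dim probe sets can show.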

Other observations

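Of 28 amino acid response and 35 endoplasmic reticulum folding genes, 13 and 22 were called higher with CsA at 12 h, with medians of 0.19 and 0.26, and the medians were 0.27 and 0.27 at 24 h and 0.26 and 0.31 at 48 h. At 11 days 22 amino acid response genes and 1 folding gene were higher. Among genes chosen after their values were seen, Sars rose by 0.37, 0.41, 0.44 and 0.52 and Atf4 by 0.29, 0.34, 0.38 and 0.33 in order of time, while Sec61a1 was at 0.29, 0.28, 0.31 and 0.03.

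These lists were chosen after the data were seen, and the tests were run on members whose change had not been seen, 14 amino acid response and 28 folding genes. At 11 days their medians, 0.282 and -0.0244, differed by 0.306 (95% bootstrap interval 0.189 to 0.404, 9 of 14 and 1 of 28 called higher). At 12 h the difference was -0.0903 (-0.195 to -0.0175, 4 of 14 and 15 of 28 called higher), so an excess of amino acid response genes was not there from the start. Genes are not independent replicates, which can make these intervals too narrow. Members of a list can move together, so the unseen members on these arrays are no independent test. As a hypothesis, found and tested on the same arrays, amino acid response genes may stay raised with CsA for longer than folding genes. No test of a mechanism was run, and a change in the cells present stays open.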
